A study of Homo sapiens with 6 samples.

How the data were processed

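RNA was sequenced from MDA-MB-231 cells after 24 h with DMSO or with AF-EAE at 75 or 150 µg/ml, with 2 libraries per group and 6 in all. The labels number the libraries of a group as biological replicates. Whether they came from separate cultures is not given in the sources used here, so the p-values measure the spread between these libraries. Per the labels' protocols, total RNA was isolated with a Vazyme extraction reagent and libraries were made with a NEBNext Ultra RNA kit. Sequencing was on an Illumina NovaSeq instrument, per the series description. Whether RNA was selected by its poly(A) tail and whether the libraries keep the strand are not given in the sources used here. Reads of a gene and of its antisense partner are therefore not separated with certainty.

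The deposited values are raw read counts per gene, 1 file per library, with 60651 gene rows and 5 summary rows. Per the submitters' processing notes, the tools were HISAT2 2.2.1 and HTSeq 2.0.2 and the genome build was hg38. The order of the steps, the counting options, the annotation release and any trimming are not given in the sources used here. The summary rows name no gene and were left out of library sizes and tests. Reads outside genes made up 6.32% and 6.72% of all counted reads in the DMSO libraries, 6.44% and 7.23% at 75 µg/ml and 7.98% and 7.73% at 150 µg/ml. Reads assigned to no single gene because genes overlap made up 10.95% to 11.48%. A gene that overlaps another therefore loses reads, and its level in CPM (gene counts scaled to a common library total) is a lower estimate. The summary row for multiply aligned reads held 0, and how such reads were treated is not given in the sources used here, so genes with near-identical copies are uncertain.

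Gene symbols were available for 60437 rows, which hold 99.94% of the gene counts. Coordinates are those of GENCODE 29 on GRCh38 (hg38), and 58361 rows matched it by identifier without the version. Gene counts per library ran from 15621103 to 17113722, so that 3 counts in a library correspond to 0.175 to 0.192 CPM. This floor and the intervals given cover counting error only.

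Differences were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, edgeR's default filter on low counts by group, and the quasi-likelihood F-test with Benjamini-Hochberg adjustment at 0.05. All 6 libraries entered the fit, with a mean per group and no other term, which leaves 3 residual degrees of freedom and added 13.8 prior degrees of freedom. Of the gene rows, 15589 were tested and 45062 were removed by the filter. The common dispersion was 0.00258, a biological coefficient of variation of 5.08%. Values are TMM-scaled CPM, and means are given with the SD of the 2 libraries. The standard error (SE) of a log2 fold change was derived from its F statistic. Each of the 3 pairs of groups was compared.

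Gene sets were 35 hand-written lists with 1021 symbols, of which 1020 were on a row. Lists with 5 or more tested members were compared with all other genes by camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. This covered 34 lists, and the leukocyte marker list had too few tested members. Camera with a correlation estimated per list and fry, which tests whether a set's genes move on balance in 1 direction without comparing them with other genes, were alternatives.

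The genes named in the text follow a rule. SKP2 and CDKN1A are given in every comparison. Then come the 6 largest rises and 6 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of 10 CPM or more over all libraries and no overlap between the groups' libraries. Then, for the 10 moved lists with the smallest camera p, come the 2 members with the smallest p that changed in the list's direction. Members named because they moved against the direction of their list, and all other genes outside this rule, were chosen after their values were seen. Some genes that the rule takes are not reported here. The groups, the tests, the lists, this rule and the alternatives were fixed before the data were examined.

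The alternatives were DESeq2 size factors and total counts in place of TMM, no filter and a stricter filter on low counts (5 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, a fit of only the 2 groups compared, the replicate number as a block, each library left out in turn, an adjusted p of 0.01, and an absolute log2 fold change of 1 or more. The agreement of the 2 doses was set against 50 simulations of unchanged groups that shared the DMSO libraries.

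The tests were tested on simulated data, with 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale among 14714 genes. For 75 µg/ml against DMSO, edgeR recovered 68.7%, 86.6% and 97% of them, and 7.18% of its calls were false. For 150 µg/ml against DMSO it recovered 65.7%, 77.6% and 92.4%, and 6.25% of its calls were false. The false share was 3.18% and 3.7% with DESeq2 and 4.68% and 6.29% with limma-voom. A simulated shift of 0.5 in the tubulin list gave camera an adjusted p of 2.3e-14. Genes were simulated independently of each other, while the correlation estimated for the tubulin list in the data was 0.167. Far fewer genes were changed than were called in the data. The simulation therefore does not show how camera behaves with correlated genes, and its rates may not carry over to the data. Scripts used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.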

Results

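MDA-MB-231 is an established human triple-negative breast cancer cell line. The cells received DMSO, the solvent control, or AF-EAE, an ethyl acetate extract of the plant Antenoron filiforme whose constituents are not given in the sources used here, at 75 or 150 µg/ml for 24 h. RNA profiles were taken from 2 libraries per group. Counts in genes came to 17113722 and 16414083 in the DMSO libraries, 16152680 and 16407218 at 75 µg/ml and 15621103 and 16317904 at 150 µg/ml. Libraries of a group correlated at 0.990 (DMSO), 0.991 (75 µg/ml) and 0.991 (150 µg/ml) over log2 CPM across genes, and each correlated less with any library of another group. The groups separated along the first principal component, which held 61.7% of the variance. Replicates were not copies of each other, since their counts differed by more than sampling noise, with a chi-square per degree of freedom of 3.432, 2.699 and 3.37.

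The series title names the SKP2/P21 axis and proliferation, and the comparison of 75 µg/ml with DMSO asked how transcripts of that axis and other genes differed at the lower dose. SKP2 fell and CDKN1A rose. SKP2 encodes the F-box subunit with which an SCF ubiquitin ligase recognises cell cycle inhibitors. Its level was 92.8 ± 4.52 CPM in DMSO and 52.6 ± 1.97 CPM at 75 µg/ml (SD, n = 2 each), a log2 fold change of -0.82 (SE 0.0712, adjusted p = 1.0e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CDKN1A encodes p21, an inhibitor of cyclin-dependent kinases. It went from 118 ± 0.364 to 267 ± 7.61 CPM (SD, n = 2 each), a log2 fold change of 1.19 (SE 0.0529, adjusted p = 3.2e-11, the same edgeR test with Benjamini-Hochberg adjustment). SKP2 (ENSG00000145604.17) lies on the plus strand of chromosome 5, from 36151989 to 36184319, and CDKN1A (ENSG00000124762.14) on the plus strand of chromosome 6, from 36676460 to 36687339 (GRCh38).

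In the list of the SKP2-p21 axis, 9 of 13 measured genes fell, CDKN1A rose and 3 did not pass the test (camera adjusted p = 0.00179, and adjusted p = 0.148 with an estimated correlation). SKP2 and CDKN1A are members of it and stand in the series title, so the list is not independent evidence of its direction. The genes that fell included, chosen after their values were seen, CDK6 (log2 fold change -1.18, SE 0.053) and CCND1 (-0.51, SE 0.0502), which encode a cyclin-dependent kinase and its D-type cyclin partner. CDKN1B, which encodes the related inhibitor p27, was at 60.2 ± 2.51 CPM in DMSO and 57.5 ± 4.22 CPM at 75 µg/ml (SD, n = 2 each), with an adjusted p of 0.554 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CKS1B and SKP1 were the other members not past the test.

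Genes of DNA replication and division were lower. Of 46 genes of G1/S and DNA replication, 41 fell and 5 did not pass the test (median log2 fold change -0.57, camera adjusted p = 1.9e-17, adjusted p = 0.0671 with an estimated correlation). UNG, a uracil-DNA glycosylase, fell from 148 ± 1.08 to 54.6 ± 3.28 CPM, and MCM6, a subunit of the replicative helicase, from 190 ± 4.1 to 78.0 ± 1.52 CPM (SD, n = 2 each). Mitosis genes fell in 39 of 54 cases (median -0.35, camera adjusted p = 6.3e-11, adjusted p = 0.216 with an estimated correlation). Among them were the contractile ring protein gene ANLN (log2 fold change -0.71, SE 0.0434) and MKI67, a proliferation antigen gene (-0.76, SE 0.0495). In homologous recombination and Fanconi repair, 16 of 30 fell and 3 rose (camera adjusted p = 0.00373, adjusted p = 0.148 with an estimated correlation), while under total counts 8 fell and 4 rose with a median of -0.07. The 3 that rose, chosen after their values were seen, were BRCA1 (0.47), FANCD2 (0.43) and CHEK2 (0.52), each a gene of DNA damage signalling or repair. Replication-dependent histone genes did not move as a list (1 rose and 2 fell of 12, camera adjusted p = 0.663). Their median of -0.05 turned to 0.08 under total-count scaling, and their mean was 0.03.

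Genes of several stress and xenobiotic responses were higher. Among 32 ATF4 and integrated stress response genes, 29 rose (median 0.82, camera adjusted p = 4.1e-12, adjusted p = 0.127 with an estimated correlation). SLC7A1, a cationic amino acid transporter gene, and ATF5, a transcription factor gene of the same response, were the 2 that fell (-0.47 and -0.79) and were chosen after their values were seen. SLC7A11, which encodes the cystine transporter subunit xCT and belongs to both the ATF4 and the NRF2 list, rose from 260 ± 5.64 to 694 ± 2.87 CPM (SD, n = 2 each). ADM2, a peptide hormone gene, rose from 4.38 ± 0.662 to 31.6 ± 0.00251 CPM (SD, n = 2 each). NRF2 targets rose in 25 of 30 cases, and the transketolase gene TKT fell (median 0.76, camera adjusted p = 4.4e-11, adjusted p = 0.123 with an estimated correlation). FTH1, the ferritin heavy chain gene, rose 2.72-fold. It has many processed copies and 62.4% of its exonic length overlaps other genes, so its level is uncertain. AHR targets rose in 8 of 9 cases (median 0.88, camera adjusted p = 2.0e-06, adjusted p = 0.159 with an estimated correlation). The AHR-induced monooxygenase gene CYP1B1 went from 16.5 ± 0.394 to 146 ± 2.56 CPM, 8.83-fold (SD, n = 2 each). Of 36 lysosome and autophagy genes, 25 rose and 1 fell (median 0.30, camera adjusted p = 2.0e-08, adjusted p = 0.106 with an estimated correlation). The autophagy receptor gene SQSTM1 was at 1.77-fold and the protease gene CTSL at 2.02-fold. Unfolded protein response genes rose in 13 of 25 cases (median 0.23, camera adjusted p = 0.00039, adjusted p = 0.315 with an estimated correlation), and in 21 under total counts.

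Inflammatory and interferon genes rose as well. Of 25 NF-kB and cytokine genes, 23 rose (median 1.02, camera adjusted p = 1.2e-10, adjusted p = 0.109 with an estimated correlation). NFKB1, which encodes an NF-kB subunit and was chosen after its values were seen, fell by 0.29 on the log2 scale. CSF3, the gene of granulocyte colony-stimulating factor, rose from 248 ± 10.8 to 1244 ± 77.4 CPM. The chemokine gene CXCL2, whose close relatives can share reads with it, rose from 12.9 ± 1.84 to 65.4 ± 1.53 CPM (SD, n = 2 each). Of 35 interferon-stimulated genes, 22 rose and 13 did not pass the test (median 0.85, camera adjusted p = 2.2e-08, adjusted p = 0.289 with an estimated correlation). They included IFI44 (3.06-fold) and STAT2, a signal transducer of the interferon response (1.71-fold).

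Lower groups also included YAP/TAZ-TEAD targets, nucleolar genes and splicing factors. Of 23 YAP/TAZ-TEAD targets, 22 fell (median -0.72, camera adjusted p = 2.8e-12, adjusted p = 0.0671 with an estimated correlation). ANKRD1, a transcriptional cofactor gene, fell from 534 ± 0.441 to 143 ± 2.82 CPM and CCN2, the connective tissue growth factor gene, from 260 ± 2.43 to 53.2 ± 1.3 CPM (SD, n = 2 each). Among 41 ribosome biogenesis and MYC target genes, 34 fell (median -0.49, camera adjusted p = 1.9e-13, adjusted p = 0.216 with an estimated correlation). The nucleolar genes NPM1 and NOLC1 were at -0.68 and -0.79. NPM1 has processed copies and is uncertain to that extent. Splicing factors fell in 23 of 31 cases (median -0.33, camera adjusted p = 2.2e-08, adjusted p = 0.106 with an estimated correlation). The RNA-binding protein genes HNRNPD and HNRNPDL were at -0.64 and -0.67. Cytosolic ribosomal protein genes fell in 44 of 72 cases (median -0.18, camera adjusted p = 9.4e-08, adjusted p = 0.479 with an estimated correlation), while under total counts 15 fell and 3 rose with a median of -0.06.

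Among the largest rises outside these lists were the antisense transcript ZMIZ1-AS1 (15.1-fold), the stress cytokine gene GDF15 (12.3-fold) and the cytokine gene IL24 (9.48-fold), each with n = 2 per group. ZMIZ1-AS1 lies on chromosome 10 from 78943328 to 79067895. The largest falls were MIR137HG, a microRNA host gene on chromosome 1 from 97933474 to 98049863 (from 61.3 ± 4.54 to 6.91 ± 0.344 CPM), CCN2 and the Wnt antagonist gene DKK1 (from 237 ± 13.5 to 49.7 ± 0.653 CPM; SD, n = 2 each). Next were the matrix glycoprotein gene THBS1 (from 306 ± 9.16 to 70.7 ± 3.95 CPM), the growth factor gene TGFB2 (from 65.6 ± 6.25 to 15.9 ± 0.576 CPM) and ANKRD1 (SD, n = 2 each).

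Cholesterol genes under SREBP2 fell in 17 of 27 cases with 1 higher (median -0.25, adjusted p = 0.315 with an estimated correlation; 9 lower and 2 higher under total counts) and fatty acid genes under SREBP1 in 10 of 20 with 3 higher (-0.22, adjusted p = 0.315 with an estimated correlation). Glycolysis genes fell in 10 of 20 cases with 4 higher (-0.18, adjusted p = 0.41 with an estimated correlation; 6 lower and 6 higher with a median of -0.06 under total counts) and heat shock genes in 15 of 21 with 4 higher (-0.32, adjusted p = 0.315 with an estimated correlation). The heat shock genes that rose, chosen after their values were seen, were the chaperone genes HSPA6 (1.53), HSPB8 (0.85) and DNAJB4 (0.35) and the co-chaperone gene BAG3 (0.20). Of 13 mitochondrial DNA-encoded protein genes, 10 fell and MT-ND1 and MT-ND2, complex I subunit genes chosen after their values were seen, rose (median -0.52, camera adjusted p = 0.000785, adjusted p = 0.315 with an estimated correlation). Nuclear respiratory chain genes fell in 11 of 53 cases with 1 higher (median -0.07, adjusted p = 0.589 with an estimated correlation). Under total counts 5 fell and 7 rose, their median was 0.05 and the list no longer passed (camera adjusted p = 0.417). Housekeeping reference genes fell in 11 of 25 cases with 3 higher (median -0.13, adjusted p = 0.334 with an estimated correlation). This call was also lost under total counts (camera adjusted p = 0.148), where 5 fell and 7 rose. Of 27 hypoxia targets, 13 rose and 4 fell (median 0.33, adjusted p = 0.572 with an estimated correlation). Without DMSO replicate 1 that list no longer passed (camera adjusted p = 0.165).

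No shift against other genes passed camera's threshold for p53 targets (11 rose and 4 fell of 29, adjusted p = 0.126), BCL2 family and caspase genes (8 and 10 of 29, adjusted p = 0.936), or immediate early genes (12 and 5 of 32, adjusted p = 0.456). The same held for collagens, matrix and mesenchymal genes (12 and 11 of 35, adjusted p = 0.707), epithelial genes (6 and 3 of 23, adjusted p = 0.159), TGF-beta targets (9 and 5 of 22, adjusted p = 0.283) or metallothioneins (3 and 1 of 7, adjusted p = 0.248). The BCL2 list had a median of 0.07 and a mean of 0.25, while its test pointed downward. Under total counts 13 of its genes rose and 7 fell, with a median of 0.20. Tubulins (3 rose and 4 fell of 10, adjusted p = 0.434) had a median of -0.08 that became 0.05 under total counts, and a mean of 0.11. Markers of other cell types did not move as lists. Luminal breast markers rose in 5 and fell in 2 of 9 cases (camera adjusted p = 0.663) and fibroblast and endothelial markers in 2 and 2 of 7 (camera adjusted p = 0.795), where the test pointed downward against a median of 0.25.

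In all, 6015 of 15589 genes (38.6%) changed at 75 µg/ml by edgeR's quasi-likelihood test, 2989 higher and 3026 lower, with a median absolute log2 fold change of 0.44. Under total counts 4501 were higher and 1816 lower, where the median log2 fold change of all genes was 0.14 against 0.01 with TMM. Counts of direction are therefore relative to the scaling. An absolute log2 fold change of 1 or more was reached by 740 higher and 196 lower genes. Camera moved 23 of the 34 lists, 8 up and 15 down. With an estimated correlation camera moved 0 lists, with 10 at an unadjusted p under 0.05, and fry moved 27. Adjusted over the list alone, the members that fell were 43 for G1/S, 40 for mitosis, 36 for ribosome biogenesis, 48 for ribosomal proteins, 24 for splicing factors and 9 for the SKP2-p21 axis. Those that rose, adjusted over the list alone, were 26 for NRF2 targets, 9 for AHR targets, 26 for lysosome and autophagy, 29 for ATF4, 23 for NF-kB and 22 for interferon-stimulated genes.

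**Figure D1:**
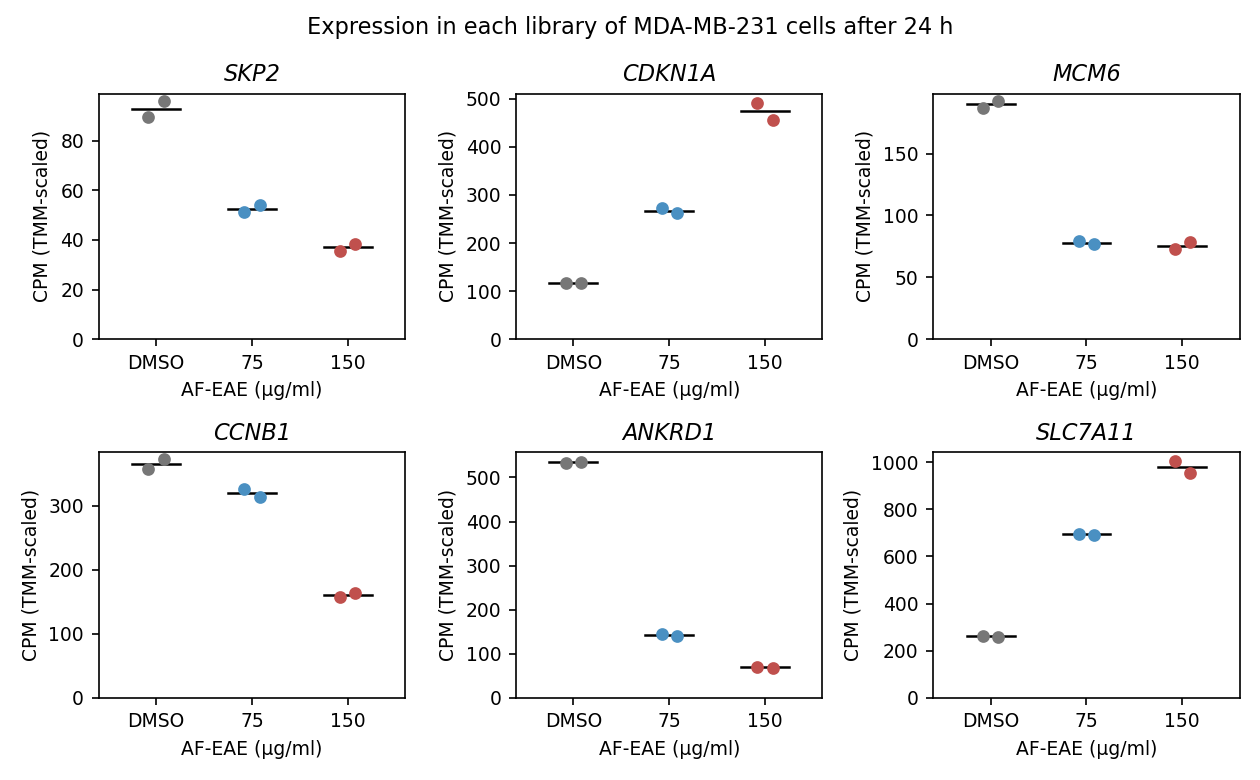
TMM-scaled CPM (y axis) of 6 genes in each library (points) by group (x axis, AF-EAE in µg/ml), with the mean of the 2 libraries as a line. SKP2 went from a mean of 92.8 CPM in DMSO to 52.6 and 37.1 CPM, CDKN1A from 118 to 267 and 474 CPM, and the libraries of the 3 groups do not overlap for either.

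At 150 µg/ml against DMSO the same question was asked of the higher dose. SKP2 fell from 92.8 ± 4.52 to 37.1 ± 1.91 CPM and CDKN1A rose from 118 ± 0.364 to 474 ± 25.4 CPM (SD, n = 2 each). The log2 fold changes were -1.32 for SKP2 (SE 0.0736, adjusted p = 1.2e-10) and 2.01 for CDKN1A (SE 0.0527, adjusted p = 1.5e-14) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the SKP2-p21 axis list 10 of 13 genes fell and CDKN1A rose (camera adjusted p = 0.000909, adjusted p = 0.117 with an estimated correlation), with the same limit on independence. CDK6 (log2 fold change -1.34) and CCND1 (-1.10), chosen after their values were seen, were among those that fell, and CDKN1B (-0.18) and SKP1 (-0.03) were not past the test.

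Mitosis genes fell in 51 of 54 cases, with a median log2 fold change of -0.88 (camera adjusted p = 6.5e-20, adjusted p = 0.117 with an estimated correlation). KIF20A, a mitotic kinesin gene on chromosome 5 from 138178719 to 138187715, fell from 205 ± 12.8 to 45.8 ± 2.67 CPM and ANLN from 641 ± 10.5 to 240 ± 2.74 CPM (SD, n = 2 each). Of 46 G1/S genes, 43 fell (median -0.74, camera adjusted p = 6.7e-15, adjusted p = 0.0787 with an estimated correlation). UHRF1, which links DNA methylation to replication, was at -1.59 and UNG at -1.86. Repair genes of homologous recombination fell in 17 of 30 cases with 4 higher (median -0.31, adjusted p = 0.117 with an estimated correlation), and in 9 with 4 higher under total counts. The 4 were BRCA1 (0.74), BRCA2 (0.19), FANCD2 (0.31) and CHEK2 (0.53), chosen after their values were seen.

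ATF4 genes rose in 30 of 32 cases (median 1.32, camera adjusted p = 4.9e-13, adjusted p = 0.117 with an estimated correlation), and SLC7A1 and ATF5 again fell. SLC7A11 reached 980 ± 35 CPM, and TRIB3, a pseudokinase gene of the stress response, went from 48.1 ± 3.19 to 241 ± 14 CPM (SD, n = 2 each). NRF2 targets rose in 26 of 30 cases, with TKT and the thioredoxin gene TXN lower (median 1.03, camera adjusted p = 2.2e-09, adjusted p = 0.117 with an estimated correlation). FTH1 rose 3.76-fold. All 9 measured AHR targets rose (median 1.21, adjusted p = 0.145 with an estimated correlation). NF-kB and cytokine genes rose in 20 of 25 cases with NFKB1 lower (median 1.07, camera adjusted p = 3.5e-07, adjusted p = 0.117 with an estimated correlation). CXCL2 rose 9.77-fold, and the chemokine gene CXCL8 went from 70.3 ± 6.28 to 581 ± 84.4 CPM (SD, n = 2 each). Interferon-stimulated genes rose in 25 of 35 cases, with the restriction factor genes IFITM2 and IFITM3 lower (median 1.11, camera adjusted p = 3.5e-07, adjusted p = 0.259 with an estimated correlation). IFI44 was at 4.77-fold, and the ubiquitin-like modifier gene ISG15 had a log2 fold change of 1.43. Immediate early genes rose in 19 of 32 cases with 5 lower (median 0.55, adjusted p = 0.145 with an estimated correlation). Lysosome and autophagy genes rose in 20 of 36 with 1 lower (0.32, adjusted p = 0.117 with an estimated correlation; 31 higher under total counts) and unfolded protein response genes in 16 of 25 with 2 lower (0.34, adjusted p = 0.31 with an estimated correlation).

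All 23 measured YAP/TAZ-TEAD targets fell (median -0.98, camera adjusted p = 2.9e-11, adjusted p = 0.0787 with an estimated correlation). ANKRD1 was at 69.3 ± 1.35 CPM against 534 ± 0.441 CPM and CRIM1, a membrane protein gene, at 233 ± 9.62 against 839 ± 22 CPM in DMSO (SD, n = 2 each). Ribosome biogenesis genes fell in 35 of 41 cases with 1 higher (median -0.63, camera adjusted p = 2.4e-11, adjusted p = 0.23 with an estimated correlation). The nucleolar genes NPM1 and NCL were at -0.98 and -0.91. Ribosomal protein genes fell in 58 of 72 cases (median -0.30, camera adjusted p = 4.2e-10, adjusted p = 0.407 with an estimated correlation). RPL7A was at -0.59 and RPS26 at -0.69, both with processed copies that make them uncertain. Under total counts 34 of them fell and 2 rose, with a median of -0.11.

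Protein genes of mitochondrial DNA fell in 12 of 13 cases (median -1.40, camera adjusted p = 4.1e-07, adjusted p = 0.152 with an estimated correlation). MT-CYB, a complex III subunit gene, went from 3272 ± 159 to 1003 ± 43.1 CPM and MT-CO2, a complex IV subunit gene, from 4565 ± 78.7 to 1490 ± 125 CPM (SD, n = 2 each). The mitochondrial ribosomal RNAs, chosen after their values were seen, moved the other way. MT-RNR2 rose from 2519 ± 254 to 5172 ± 81.6 CPM at 75 µg/ml and 7585 ± 73.8 CPM at 150 µg/ml (SD, n = 2 each), log2 fold changes of 1.04 and 1.59 with adjusted p = 1.2e-10 and 1.5e-13 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. MT-RNR1 rose by 0.99 and 1.57 on the log2 scale. Nuclear respiratory chain genes fell in 29 of 53 cases with 1 higher (median -0.23, adjusted p = 0.314 with an estimated correlation), while under total counts 13 fell and 6 rose with a median of -0.04.

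**Figure D2:**
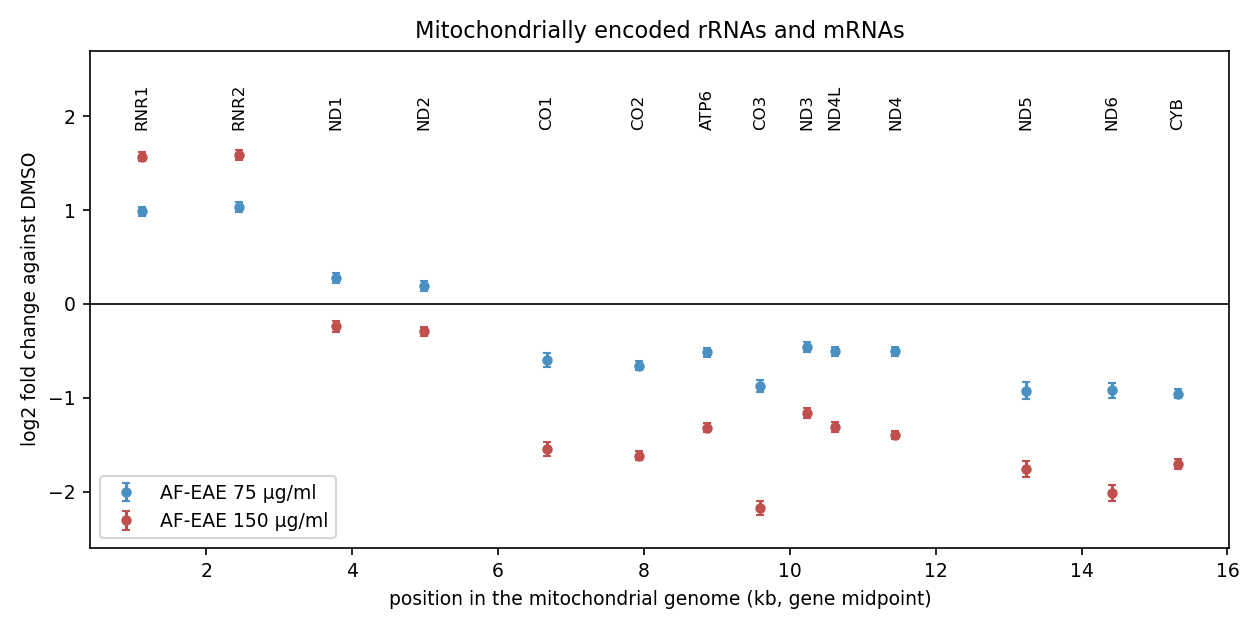
Log2 fold change against DMSO (y axis, SE as bars) of mitochondrial rRNA and protein genes at their midpoints in the mitochondrial genome (x axis, kb), for 75 µg/ml (blue) and 150 µg/ml (red); MT-ATP8, near 2 CPM, is left out. Both rRNAs were higher at both doses, MT-ND1 and MT-ND2 were higher at 75 µg/ml and lower at 150 µg/ml, and the genes from MT-CO1 onwards were lower at both, down to -2.18 for MT-CO3 at 150 µg/ml.

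Among the largest rises were ZMIZ1-AS1 (29.4-fold), GDF15 (26.9-fold), EGR1, an immediate early transcription factor gene (21.6-fold), IL24 (20.5-fold) and ADM2 (13.97-fold). EGR1 stood at 74.8 and 29.7 CPM in the 2 libraries at 150 µg/ml. The largest falls were in MIR137HG (log2 fold change -3.88), TGFB2 (-3.53), SERTAD4 (-3.32), ANKRD1 (-2.95), THBS1 (-2.91) and DKK1 (-2.85). TGFB2 shares 26.6% of its exonic length with other genes on its strand, which makes its level uncertain.

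Glycolysis genes fell in 14 of 20 cases with 2 higher (median -0.39, adjusted p = 0.259 with an estimated correlation). Heat shock genes fell in 17 of 21 cases with HSPB8 and DNAJB4 higher (-0.44, adjusted p = 0.31 with an estimated correlation). SREBP2 genes fell in 18 of 27 with 3 higher (-0.38, adjusted p = 0.31 with an estimated correlation) and SREBP1 genes in 14 of 20 with 4 higher (-0.35, adjusted p = 0.31 with an estimated correlation). Under total counts 12 SREBP2 genes were lower and 6 higher, with a median of -0.19, and 9 SREBP1 genes were lower and 4 higher. Splicing factors fell in 22 of 31 cases (-0.36, adjusted p = 0.117 with an estimated correlation). Housekeeping reference genes fell in 14 of 25 cases with 4 higher (median -0.23, adjusted p = 0.259 with an estimated correlation). Under total counts 10 of them fell and 7 rose, with a median of -0.05. ACTB, the beta-actin gene often used as a reference and chosen after its values were seen, fell from 4902 ± 60.7 to 2090 ± 71.8 CPM (SD, n = 2 each).

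Lists without a shift past camera's threshold were hypoxia targets (12 rose and 9 fell of 27, adjusted p = 0.528), p53 targets (13 and 6 of 29, adjusted p = 0.0606), BCL2 family and caspases (14 and 10 of 29, adjusted p = 0.571), and histones (1 and 4 of 12, adjusted p = 0.258). With a stricter filter on low counts camera called histones lower (adjusted p = 0.0243, median -0.50), tubulins lower (adjusted p = 0.0418) and p53 targets higher (adjusted p = 0.0311). Others were epithelial genes (6 and 4 of 23, adjusted p = 0.719), TGF-beta targets (9 and 8 of 22, adjusted p = 0.813; median 0.30, mean -0.11) and tubulins (3 and 6 of 10, adjusted p = 0.195; median -0.38, mean 0.02). Metallothioneins (3 and 2 of 7, adjusted p = 0.973) had a median of -0.01 that became 0.18 under total counts, and a mean of 0.15. Collagens, matrix and mesenchymal genes (11 rose and 18 fell of 35, adjusted p = 0.14) passed as lower under total counts (camera adjusted p = 0.0447). Luminal breast markers rose in 3 and fell in 4 of 9 cases (camera adjusted p = 0.571). Their median of -0.12 became 0.07 under total counts, and their mean was 0.09. Of the 7 fibroblast and endothelial markers, 3 fell (camera adjusted p = 0.291).

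At 150 µg/ml 8022 genes (51.5%) changed by edgeR's quasi-likelihood test, 4022 higher and 4000 lower, against 6031 higher and 2542 lower under total counts, where the median log2 fold change of all genes was 0.22 (0.03 with TMM). The median absolute log2 fold change was 0.56, and 1205 higher and 622 lower genes reached an absolute log2 fold change of 1. Camera moved 23 of 34 lists, 8 up and 15 down. With an estimated correlation camera moved 0 lists, with 11 at an unadjusted p under 0.05, and fry moved 31. Adjusted over the list alone, 59 ribosomal protein, 31 respiratory chain and 11 SKP2-p21 axis genes fell and 20 immediate early genes rose. The counts for mitosis (51), G1/S (43), ATF4 (30), NRF2 (26) and YAP/TAZ-TEAD (23) equalled those over all genes.

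**Figure D3:**
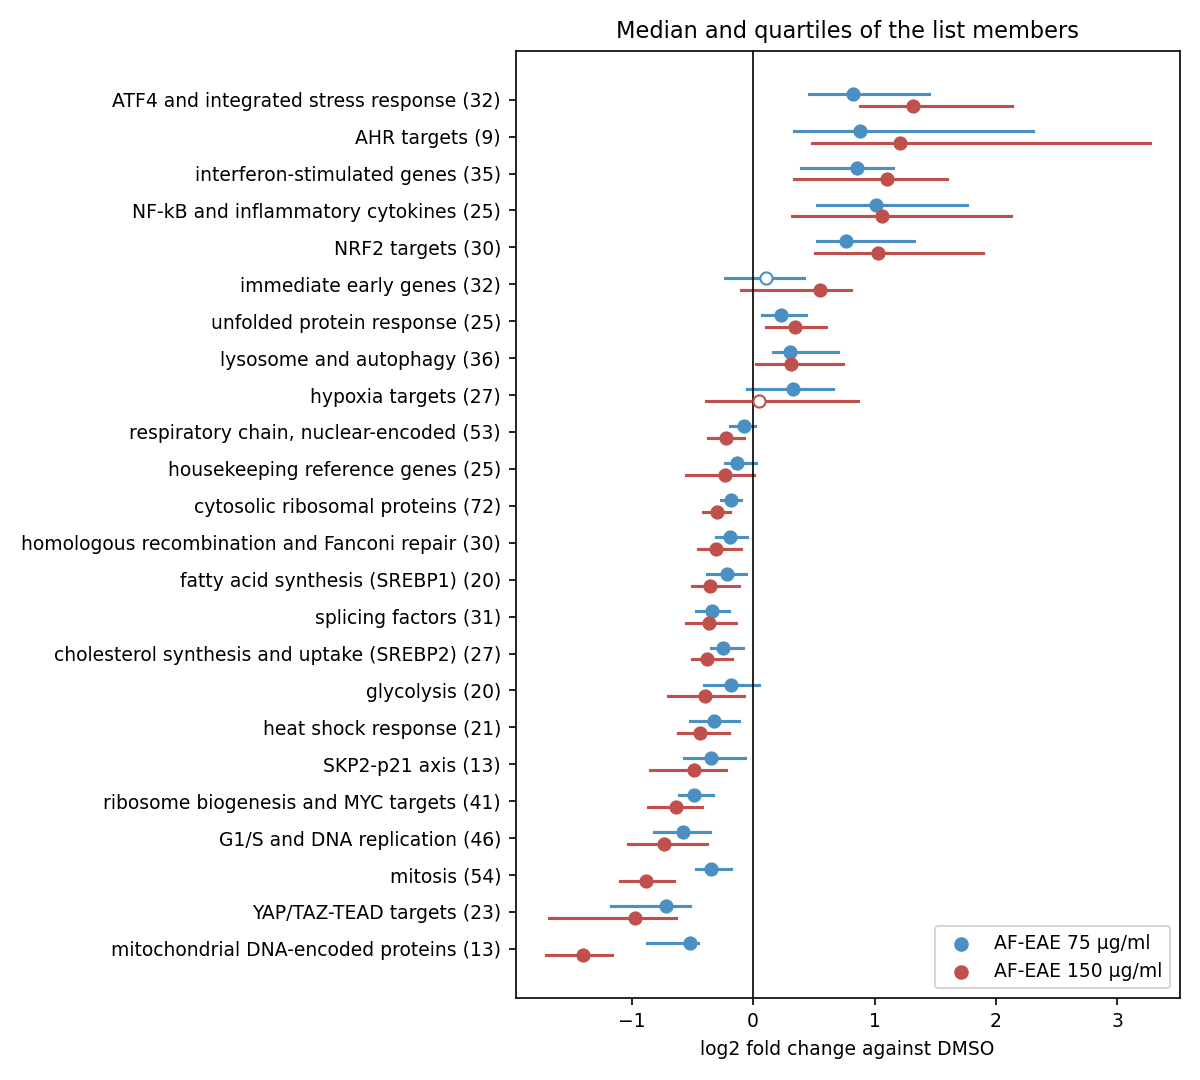
Median log2 fold change against DMSO of the members of each list (x axis) with the quartiles as bars, at 75 µg/ml (blue) and 150 µg/ml (red), for lists past camera's threshold at either dose (number of tested members in brackets; open points did not pass at that dose). The highest median was that of NF-kB and cytokine genes at 75 µg/ml (1.02) and of ATF4 genes at 150 µg/ml (1.32), and under total counts the respiratory chain median at 75 µg/ml turned from -0.07 to 0.05.

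The comparison of 150 with 75 µg/ml asked what differed between the doses. SKP2 fell further, from 52.6 ± 1.97 to 37.1 ± 1.91 CPM, and CDKN1A rose further, from 267 ± 7.61 to 474 ± 25.4 CPM (SD, n = 2 each). The log2 fold changes were -0.50 for SKP2 (SE 0.0761, adjusted p = 0.000142) and 0.83 for CDKN1A (SE 0.0495, adjusted p = 8.5e-09) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Their list had 6 of 13 genes lower and CDKN1A higher and did not pass camera's threshold (adjusted p = 0.067), with 2 lower and 1 higher under total counts.

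Mitosis genes fell in 51 of 54 cases from the lower to the higher dose (median -0.58, camera adjusted p = 4.3e-28, adjusted p = 0.144 with an estimated correlation). G1/S genes fell in 18 of 46 cases with the replication licensing gene CDC6 higher (median -0.17, camera adjusted p = 3.5e-05, adjusted p = 0.144 with an estimated correlation). KIF20A went from 131 ± 4.83 to 45.8 ± 2.67 CPM and CCNB1, the cyclin B1 gene, from 319 ± 9.36 to 160 ± 4.35 CPM (SD, n = 2 each). In G1/S, UHRF1 fell by 0.58 and the thymidine kinase gene TK1 by 0.33 on the log2 scale. ATF4 genes rose in 29 of 32 cases (median 0.49, camera adjusted p = 1.8e-16, adjusted p = 0.144 with an estimated correlation). SESN2, a stress sensor gene, was at 2.40-fold and TRIB3 at 1.86-fold. The glutathione-degrading enzyme gene CHAC1 was among the largest rises at 2.39-fold.

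Immediate early genes rose in 19 of 32 cases with FOSL2, an AP-1 subunit gene, lower (median 0.29, camera adjusted p = 2.7e-05, adjusted p = 0.144 with an estimated correlation). They included the phosphatase genes DUSP5 (1.53-fold) and DUSP1 (2.08-fold). EGR1, a member of this family, rose from 6.65 ± 2.75 to 52.3 ± 31.9 CPM and the stress-induced transcription factor gene ATF3 from 9.91 ± 0.0788 to 29.5 ± 8.5 CPM (SD, n = 2 each). The epidermal growth factor family gene EREG (2.40-fold) and the hexokinase domain gene HKDC1 (2.33-fold) also rose. NRF2 targets rose in 14 of 30 cases with 3 lower (median 0.24, adjusted p = 0.27 with an estimated correlation). SLC7A11 was at 1.41-fold, and the aldo-keto reductase gene AKR1C1, which is nearly identical to a neighbour and so uncertain, at 4.39-fold. AHR targets rose in 6 of 9 cases (median 0.27, adjusted p = 0.312 with an estimated correlation) and interferon-stimulated genes in 12 of 35 with 3 lower (0.22, adjusted p = 0.395 with an estimated correlation). Targets of p53 rose in 11 of 29 with 4 lower (0.16, adjusted p = 0.27 with an estimated correlation) and unfolded protein response genes in 10 of 25 with 2 lower (0.06, adjusted p = 0.409 with an estimated correlation).

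Mitochondrial DNA-encoded protein genes fell in 12 of 13 cases (median -0.81, camera adjusted p = 1.1e-10, adjusted p = 0.175 with an estimated correlation). MT-ND4, a complex I subunit gene, went from 3973 ± 17.8 to 2139 ± 71.8 CPM and MT-CO2 from 2893 ± 10.8 to 1490 ± 125 CPM (SD, n = 2 each). Nuclear respiratory chain genes fell in 21 of 53 cases (median -0.17, camera adjusted p = 8.5e-06, adjusted p = 0.329 with an estimated correlation), and in 12 under total counts. The ATP synthase subunit genes ATP5MC1 and ATP5F1A were at -0.57 and -0.34. Glycolysis genes fell in 14 of 20 cases with 1 higher (median -0.26, camera adjusted p = 3.5e-05, adjusted p = 0.27 with an estimated correlation). The lactate dehydrogenase gene LDHA was at -0.73 and the pyruvate kinase gene PKM at -0.47. YAP/TAZ-TEAD targets fell in 13 of 23 cases with 1 higher (median -0.30, camera adjusted p = 7.9e-05, adjusted p = 0.144 with an estimated correlation). ANKRD1 was at -1.04 and CRIM1 at -0.63. Ribosomal protein genes fell in 27 of 72 cases (median -0.12, camera adjusted p = 8.5e-06, adjusted p = 0.447 with an estimated correlation), while under total counts 8 fell. RPL7A was at -0.27 and RPS26 at -0.29. Collagens, matrix and mesenchymal genes fell in 19 of 35 cases with 1 higher (median -0.35, camera adjusted p = 0.000306, adjusted p = 0.36 with an estimated correlation).

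The largest falls between the doses included SERTAD4 (from 10.9 ± 0.637 to 3.58 ± 0.0605 CPM) and the bone morphogenetic protein antagonist gene NOG (from 21.5 ± 3.21 to 7.28 ± 2.26 CPM; SD, n = 2 each). KIF20A, NEURL1B (from 12.2 ± 2.42 to 4.31 ± 0.966 CPM) and TGFB2 (from 15.9 ± 0.576 to 5.68 ± 0.675 CPM; SD, n = 2 each) were others.

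Other shifts past camera's threshold were downward for ribosome biogenesis (15 lower and 2 higher of 41, adjusted p = 0.403 with an estimated correlation) and SREBP2 genes (7 lower and 4 higher of 27, adjusted p = 0.411 with an estimated correlation). They were downward too for housekeeping genes (9 lower and 1 higher of 25, adjusted p = 0.312 with an estimated correlation) and tubulins (6 of 10 lower, adjusted p = 0.36 with an estimated correlation). Markers of other cell types were also lower, in 5 of 9 luminal breast markers with 1 higher (median -0.30) and 2 of 7 fibroblast and endothelial markers, ENG and KDR (median -0.47), each with adjusted p = 0.27 with an estimated correlation. Lists not past the threshold were repair genes of homologous recombination (2 lower and 2 higher of 30, adjusted p = 0.067) and SREBP1 genes (5 and 1 of 20, adjusted p = 0.249). Heat shock genes (4 and 1 of 21, adjusted p = 0.121, but 4 and 4 under total counts) did not pass it either. Nor did hypoxia targets (9 and 5 of 27, adjusted p = 0.354, but 7 and 8 under total counts). Further lists not past camera's threshold, lower first, were NF-kB and cytokine genes (6 and 8 of 25, adjusted p = 0.108) and BCL2 family and caspases (2 and 10 of 29, adjusted p = 0.13). Lysosome genes (10 and 11 of 36, adjusted p = 0.138, median 0.06, mean -0.01) were another, with 5 and 15 and a median of 0.12 under total counts. The rest were epithelial genes (7 and 3 of 23, adjusted p = 0.268; median -0.12, mean 0.05), TGF-beta targets (7 and 4 of 22, adjusted p = 0.141), metallothioneins (4 and 1 of 7, adjusted p = 0.0742) and histones (1 of 12 lower, adjusted p = 0.193). Metallothioneins passed as lower under total counts (camera adjusted p = 0.0466, median -0.38). For splicing factors (7 and 1 of 31, adjusted p = 0.0968) the median of -0.04 became 0.02 under total counts, with 4 lower and 1 higher.

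Between the doses 3433 genes (22.0%) differed by edgeR's quasi-likelihood test, 1482 higher and 1951 lower, against 2206 higher and 1345 lower under total counts. Without replicate 1 at 150 µg/ml 1507 genes were called and without replicate 1 at 75 µg/ml 1990. An absolute log2 fold change of 1 was reached by 130 higher and 96 lower genes. Camera moved 21 of 34 lists, 7 up and 14 down. With an estimated correlation camera moved 0 lists, with 6 at an unadjusted p under 0.05, and fry moved 27. Adjusted over the list alone, 20 G1/S, 35 ribosomal protein and 25 respiratory chain genes fell, 31 ATF4 and 21 immediate early genes rose, and mitosis stayed at 51.

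Of all tested genes, 83.1% had log2 fold changes of the same sign at the 2 doses. Simulated groups without an effect that shared the DMSO libraries gave 66.9% on average and 67.6% at most. Of the genes higher at 75 µg/ml, 84.1% were also higher at 150 µg/ml, and of those lower, 88.2% were also lower. This made 2513 genes higher and 2669 lower at both doses, where independent lists would share 771 and 776. Unchanged simulated groups shared 0.28 and 0.30 on average. Without changed genes few are called at all, so these simulations do not show how many shared calls the common controls would give. The log2 fold changes correlated across genes at r = 0.845 (rho = 0.819), against 0.508 on average and 0.527 at most in simulations with the same DMSO libraries and no effect, and genes are not independent replicates. With 2 DMSO libraries the controls could not be split into parts of at least 2, so part of the excess in shared calls over independent lists, and of the correlation, may come from the shared controls. The covariance was 0.411, which is 0.377 above the simulated 0.0330 that the shared controls give alone. Of the genes higher at 75 µg/ml, 685 were higher again at 150 than at 75 µg/ml and 213 were lower, and of those lower at 75 µg/ml, 1051 were lower again and 139 were higher.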

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

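Of the tests in this part, those of a single scaling factor, of nuclear copies, of position in the mitochondrial genome and of p53 targets were chosen after the result was seen, while those of short RNAs and of genomic DNA were set before theirs.

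Reads outside annotated genes, which no comparison uses, took a larger share at 150 µg/ml than in the DMSO libraries: 7.98% and 7.73% against 6.32% and 6.72%. Genomic DNA was tested through 381 olfactory receptor genes, taken as silent, over 899 kb of exons. The 526500 extra reads would add 158 counts there for a genome of 3000 Mb, and the excess seen was 57.2 counts (95% limits 11.7 to 103, counting error only; 303 against 255 counts). The upper limit lies below 158, which under these assumptions argues against genomic DNA as the source of all the extra reads. The bound set in advance lies inside these limits. A part from genomic DNA and a change in unannotated or unspliced transcripts therefore cannot be told apart for these reads. The treatment itself, which is confounded with the libraries, stays open and untested.

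Mitochondrial rRNAs were higher and most mitochondrial mRNAs lower at both doses. A single scaling factor per library would shift all of them alike. Instead, the mean log2 fold change of the 2 rRNAs lay 1.53 at 75 µg/ml and 2.98 at 150 µg/ml above the median of the 13 protein genes, whose SDs were 0.488 and 0.68. A move of reads to 404 nuclear copies is argued against by a change of -229 CPM in their sum at 150 µg/ml, where the protein genes lost 25150 CPM. Weaker selection of polyadenylated RNA should raise short RNAs without a poly(A) tail. The 37 tested had medians of -0.178 and 0.068 and upper quartiles of 0.144 and 0.867 at 75 and 150 µg/ml. At 75 µg/ml 2 were higher and 2 lower, and at 150 µg/ml 3 were higher and 3 lower. Of the 37, 30 were under 1 CPM. The quartile at 150 µg/ml lies above the bound set in advance, 0.795, so weaker selection stays open for the rRNAs. It predicts no fall of mRNAs against other genes, so the fall of the 13 protein genes (medians -0.516 and -1.4) argues against it for them. A hypothesis that heavy-strand transcription may end earlier in treated cells was tested over 11 protein genes. MT-ND4L and MT-ND4, whose coordinates overlap, were counted separately. The Spearman correlation of log2 fold change with position was -0.591 at 75 µg/ml (two-sided permutation p = 0.061) and -0.536 at 150 µg/ml (permutation p = 0.094), both with a Benjamini-Hochberg value of 0.094. The hypothesis cannot be told apart from chance with so few genes. It also does not account for MT-ND6, the light-strand mRNA left out of that test, which fell by 0.92 and 2.01 on the log2 scale, unless reads of the other strand were counted there.

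CDKN1A was higher at both doses, and p21 is a classical target of p53, which is mutant in MDA-MB-231. Total-count scaling left its log2 fold change at 1.31 and 2.2 in edgeR's quasi-likelihood test, so the rise held under both scalings. The median log2 fold change of all genes was 0.141 and 0.217 under total counts, against 0.0148 and 0.029 with TMM. Scalings that differ so little could not have removed the rise, so their comparison alone cannot decide on a scaling factor as its cause. A scaling factor shifts all genes of a library alike. With TMM, however, CDKN1A moved by 1.19 and 2.01 and SKP2 by -0.82 and -1.32, while the median gene hardly moved. These values argue against a scaling factor as the cause of the rise of CDKN1A against other genes. A general rise of p53 targets was tested on 26 of them, without CDKN1A and without members of the ATF4 and NRF2 lists: 8 rose and 4 fell at 75 µg/ml and 10 rose and 6 fell at 150 µg/ml. Limma's camera gave adjusted p = 0.483 at both doses, with Benjamini-Hochberg adjustment over the 2 tests. Members went both ways, with medians of 0.0278 and 0.146 at 75 and 150 µg/ml. Their quartiles were -0.121 and 0.481 at 75 µg/ml and -0.262 and 0.652 at 150 µg/ml. The upper quartiles lay below the log2 fold changes of CDKN1A, so a rise of its size was not general among these targets. A smaller p53-wide rise and a change of CDKN1A apart from it cannot be told apart here.

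At 22 genes the calls went in opposite directions at the 2 doses against DMSO, and each also differed between 150 and 75 µg/ml in edgeR's quasi-likelihood test. Genes picked for opposite calls in the same libraries almost have to differ between the doses, so this difference is not further evidence. Among the 22 genes, chosen after their values were seen, GADD45A, a growth arrest and DNA damage gene, fell at 75 µg/ml (-0.34) and rose at 150 µg/ml (0.38). TXNIP, a glucose-responsive thioredoxin inhibitor, did likewise (-0.43 and 0.21), and RIPOR3 did the reverse (0.59 and -0.42). RIPOR3 stood at 78.4 ± 17.6 CPM in DMSO and 58.6 ± 14.9 CPM at 150 µg/ml (SD, n = 2 each). Its libraries of these groups overlapped, so its fall at 150 µg/ml is uncertain.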

How the results depend on the processing

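Every alternative reported in this part was planned, and no test here was chosen after the result was seen. SKP2 and CDKN1A kept their direction and their call under every other scaling, filter, tool and left-out library in all 3 comparisons. The counts of changed genes ran from 4787 (DESeq2) to 6317 (total counts) at 75 µg/ml, 6733 to 8573 at 150 µg/ml and 2564 to 3776 between the doses with all libraries at an adjusted p of 0.05. Requiring an absolute log2 fold change of 1 left 936, 1827 and 226 genes, and ended the calls of SKP2 at 75 µg/ml (-0.82) and between the doses (-0.50) and of CDKN1A between the doses (0.83), by the construction of that rule. At an adjusted p of 0.01, 1883 genes differed between the doses. Leaving out a library gave 4654 to 5873, 6691 to 8021 and 1507 to 3714 genes, where the lone library of a group is assumed to vary like the others, and the cause of the low end was not tested beyond the smaller number of samples. The correlation of the doses was 0.894 with the stricter filter and 0.731 to 0.870 with a library left out, and the cause was not tested. With the correlation between genes estimated per list, camera moved 0 lists in each comparison, against 10, 11 and 6 at an unadjusted p under 0.05 and 27, 31 and 27 by fry; 3 residual degrees of freedom leave that test little power. Fry put TGF-beta targets lower at 150 µg/ml (adjusted p = 0.0493) while their median was 0.30 and camera did not call them; the cause was not tested. Deviations of same-numbered libraries correlated at 0.059, 0.0412 and 0.00373, below 0.1. These correlations showed no pairing, but counting noise over all genes lowers them, so the check cannot exclude one. The replicate block gave 6292, 8194 and 3776 genes, against 6015, 8022 and 3433 without it, so an effect of the replicate number stays possible. With the block camera moved 23, 23 and 19 lists, ending its calls of SREBP2 genes (adjusted p = 0.0523) and tubulins (0.0564) between the doses. With a library left out, camera calls at 75 µg/ml were lost for hypoxia targets without DMSO replicate 1 (adjusted p = 0.165), glycolysis without DMSO replicate 2 (0.0755) and housekeeping genes without replicate 2 at 75 µg/ml (0.0658). The respiratory chain at 75 µg/ml lost its call without DMSO replicate 1 (0.222), replicate 2 at 75 µg/ml (0.176) or either replicate at 150 µg/ml (0.0579 and 0.0577). Between the doses tubulins lost theirs without DMSO replicate 1 or 2, replicate 1 at 75 µg/ml or replicate 2 at 150 µg/ml (0.0729 to 0.0897). SREBP2 genes lost theirs without replicate 1 at 75 µg/ml (0.15) or at 150 µg/ml (0.0933), and the unfolded protein response without replicate 2 at 75 µg/ml (0.166). The stricter filter, which tests fewer genes, ended camera's calls of glycolysis (0.0699), the respiratory chain (0.175) and housekeeping genes (0.121) at 75 µg/ml and of SREBP2 genes between the doses (0.0612), and gave those of histones, tubulins and p53 targets at 150 µg/ml (0.0243, 0.0418 and 0.0311). Targets of p53 at 150 µg/ml passed without replicate 1 of that group (0.0364) and without replicate 2 (0.0436), and histones between the doses without replicate 1 at 150 µg/ml (0.0163). The genes that were named by the rule and are reported kept their direction and their call under every other scaling, filter, tool and left-out library and at an adjusted p of 0.01, while 27 of the 89 named gene results did not reach an absolute log2 fold change of 1. Depth set the floor of 3 counts at 0.175 to 0.192 CPM per library, and recovery by expression level was not simulated.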

Other observations

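The genes in this part, and the tables they come from, were chosen after their values were seen, and no explanation was tested here.

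Matrix genes moved in both directions within their list. COL12A1 fell from 223 ± 13.8 to 69.8 ± 5.74 CPM at 75 µg/ml and 36.9 ± 2.55 CPM at 150 µg/ml, the basement membrane collagen gene COL4A2 from 366 ± 1.73 to 237 ± 9 and 141 ± 13.5 CPM, and the fibronectin gene FN1 from 131 ± 1.63 to 60.3 ± 3.14 and 42.7 ± 5.06 CPM (SD, n = 2 each). The matrix metalloproteinase gene MMP3 rose from 0.868 ± 0.0686 to 5.55 ± 0.111 and 15.98 ± 1.42 CPM and MMP14 from 523 ± 19.5 to 946 ± 0.761 and 931 ± 59.5 CPM (SD, n = 2 each). Genes of the cell death machinery split as well. The survival gene BCL2 had log2 fold changes of -0.79 and -1.15 and BIRC2 of -0.60 and -0.67 at 75 and 150 µg/ml. The BH3-only genes PMAIP1 (0.38 and 1.24) and BBC3 (0.56 and 1.08) and the initiator caspase gene CASP10 (0.74 and 1.06) rose at 75 and 150 µg/ml by edgeR's quasi-likelihood test. The survival gene BCL2L2 rose as well (0.33 and 0.74), while BID, a BH3-only gene (-0.42 and -0.72), and APAF1, the apoptosome scaffold gene (-0.30 and -0.54), fell at both doses. The BH3-only gene BCL2L11 fell at 75 µg/ml (-0.67) and was at -0.20 at 150 µg/ml, which did not pass.

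Some lists held large changes in both directions. SLC16A1, a monocarboxylate transporter gene, rose from 0.731 ± 0.571 to 5.98 ± 1.74 and 11.01 ± 0.104 CPM (SD, n = 2 each) while ENO1, a glycolysis gene of the same list, fell by 0.52 and 0.94 on the log2 scale. VEGFA, the vascular endothelial growth factor gene, rose from 63.2 ± 8.23 to 239 ± 9.32 and 311 ± 23.6 CPM, and DDIT4, an inhibitor of mTOR signalling, from 106 ± 21.2 to 241 ± 30.8 and 289 ± 41.1 CPM (SD, n = 2 each). In the heat shock list, the chaperone genes HSPA8 (-0.54 and -0.94) and HSP90AA1 (-0.55 and -0.65) fell and the stress chaperone gene HSPB8 rose (0.85 and 1.65).

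At 75 µg/ml, 12 of 46 G1/S genes and 0 of 54 mitosis genes had a lower log2 fold change than SKP2, and at 150 µg/ml 5 of 46 G1/S and 9 of 54 mitosis genes did. Between the doses the figure was 36 of 54 mitosis genes and 1 of 46 G1/S genes.

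Several genes that are usually abundant in dividing cells had few counts in every library: in DMSO ALDOA was at 1.31 ± 0.192 CPM, LDHB at 1.67 ± 0.0463, SDHA at 3.24 ± 0.413, NUSAP1 at 0.773 ± 0.202 and PRC1 at 0.771 ± 0.0206 CPM (SD, n = 2 each). In GENCODE 29, exons of other genes on the same strand cover 42.3% of the exonic length of ALDOA, 33.4% of LDHB, 62.2% of NUSAP1 and 57.6% of PRC1, but 0.0% of SDHA. These levels are not read as expression here.

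In 21 of 10721 genes with a mean of 5 CPM or more, the 2 libraries of a group differed 2-fold or more in at least 1 group. RNH1, a ribonuclease inhibitor gene, stood at 57.6 and 17 CPM at 75 µg/ml and 6.71 and 65.5 CPM at 150 µg/ml, and YTHDC1 at 19.1 and 2.26 CPM at 150 µg/ml.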
